A study of Mus musculus with 70 samples.

How the data were processed

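Cells positive for GFP were sorted from dissected dorsal cortices, NSC from Hes5::GFP and BP and NBN from Tbr2::GFP animals, per the labels' protocols. How BP and NBN were separated within the Tbr2::GFP line is not given in the sources used here. The deposited values are TPM per gene, estimated with kallisto 0.43.0 on mouse builds named GRCm38.p2 and mm10, per the submitters' processing notes. TPM are scaled to a common total in each library, so a large rise in a few genes lowers all others, and sequencing depth cannot be recovered. Confidence intervals and detection limits that need counts were therefore not computed, and an exact 0 means only that a gene is listed at 0. Reads were short and single-ended per the labels' protocols, so members of near-identical families such as adult globins are uncertain.

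All columns were mapped to samples by name. The file holds 23078 genes, of which 22361 identifiers were found in the reference name table. Coordinates are from a GRCm38 annotation, matched by gene identifier. Genes with a mean of at least 1 TPM in at least 1 group were tested, 15508 in all. Tests used log2(TPM + 1), so a difference understates the change of low genes. One mean per cell type and stage was fitted with limma 3.58.1 in R 4.3.3, using all 70 libraries for a shared spread (47 residual degrees of freedom) and moderated variances with a trend. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1. Contrasts gave each stage equal weight.

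A total of 26 gene lists was fixed before the data were examined, as were the groups, tests and most alternative settings. Of these lists, 25 with at least 5 tested members were tested with limma's camera, using a correlation estimated from the residuals and adjusting over the lists within a contrast. The list of 4 Y-linked genes was used only to check libraries. Named genes followed a rule: the 8 largest called differences in each direction among genes with a mean of at least 20 TPM on the higher side and a unique symbol that was not a predicted, clone, ribosomal or mitochondrial name. Cell type differences had to keep their direction at each shared stage, and changes over time needed stage means that did not overlap, which was not asked of the interaction. For the interaction the minimum of 20 TPM applied to the highest mean of any group compared, not to the mean of a side. Members of the lists were named in addition. One gene that the rule selects is not reported here.

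The fit was tested on simulated data with the spread of the 15508 genes and 200 changed genes per contrast. Of 100 genes changed by 1.5 on the log2 scale it recovered 100% for BP against NSC and 99% for the NBN time contrast. Simulated values were independent normal draws around 1 mean per gene, and the change lay above the minimum of 1. High recovery was thus near certain, and shared animals or mixed cells were not simulated. Alternatives covered the pseudocount, the filter, scaling, the variance model, library weights, stage windows, replicate numbers as blocks and each library left out. Another 4 were chosen after seeing the data: without the 4 libraries with most genes detected, with a sex term, without E15.5 and E16.5, and without PN.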

Results

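RNA sequencing measured gene expression in fluorescent cells sorted from the mouse dorsal cortex, the future neocortex. Stages ran daily from E10.5 through birth, and the last, called PN here, was day 1 after it. Neural stem cells (NSC) came from a Hes5::GFP line, in which a Notch target gene drives a green fluorescent protein. Basal progenitors (BP), which divide away from the ventricle, and newborn neurons (NBN) came from a Tbr2::GFP line. The 70 libraries comprised 33 of NSC over 10 stages, 23 of BP over 8 stages from E12.5, and 14 of NBN over 5 stages from E15.5. The 23 groups held 2 to 4 libraries each. The labels do not say whether replicates were separate animals, so p-values measure only the spread between these libraries, which may be technical in part. Replicates that differ in sex transcripts were not 1 sample split, as with NSC E16.5 replicates 1 and 2 (Xist at 323.5 and 4.637 TPM, Y-linked transcripts at 0.5519 and 139.8). Where replicates did not differ in this way the question stays open. Reporter line and the contrast of NSC with the other cells coincided and cannot be separated. Values were TPM, a transcript abundance scaled to a common total, which keeps no sequencing depth, so depth is unknown. NSC libraries listed 17810 ± 1047 genes above 0 (SD, n = 33), BP libraries 16970 ± 506 (n = 23) and NBN libraries 17330 ± 760 (n = 14).

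Hes5 and Eomes, the genes of the reporters used to sort, were examined first. Hes5 stood at 163 ± 126 TPM in NSC libraries (SD, n = 33), 4.25 ± 1.45 in BP (n = 23) and 3.51 ± 1.54 in NBN (n = 14). Eomes, which encodes Tbr2, stood at 421 ± 101 TPM in BP and 25.1 ± 16.2 in NBN, but also at 303 ± 181 in NSC libraries. One PN library carried conflicting labels, since its cell type field named basal progenitors and its title named NSC. Its Hes5 level of 441.6 TPM lay beside the other PN NSC libraries, and it was kept as NSC replicate 3. The first 3 principal components held 43.6%, 19.4% and 10.2% of the variance. In 67 of 70 libraries the most similar library belonged to the same group, and no pair held identical values. Below, the adjusted p beside a gene list is from camera with an estimated correlation, adjusted over the 25 lists of a contrast; genes were counted as changed by limma.

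**Figure D1:**
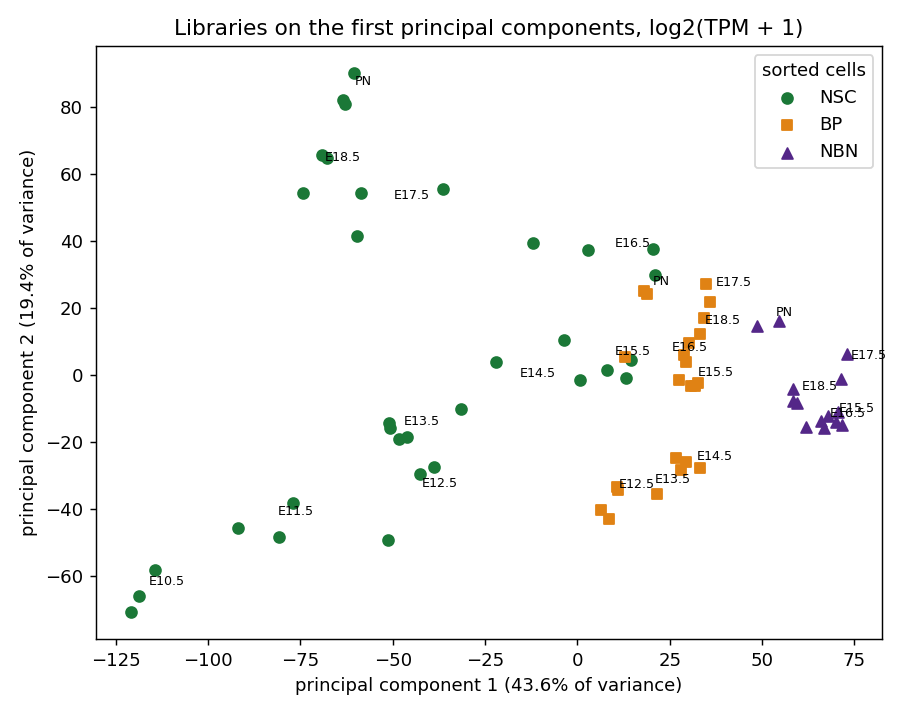
Each point is 1 library on the first principal components of log2(TPM + 1), with shape and colour for the sorted cells and text at each group mean. Component 1 holds 43.6% of the variance and component 2 holds 19.4%, and some NSC libraries of E15.5 and E16.5 lie beside BP libraries.

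BP libraries were compared with NSC libraries over the 8 shared stages, which asks how the sorted fractions differ. Genes of the stem cell state were lower in BP: 17 of 20 neural stem cell and radial glia genes were lower (adjusted p = 0.0825), including Sox9 (log2 difference -2.92 ± 0.07 SE), Slc1a3 (-3.46 ± 0.07), a glutamate transporter of radial glia, and Fabp7 (-3.72 ± 0.10), a fatty acid binding protein. Hes5 was lower (-4.90 ± 0.08), at 4.25 against 178 TPM. Cell cycle genes were lower in 24 of 28 cases (adjusted p = 0.0825), among them the mitotic genes Top2a (-1.51 ± 0.07) and Mki67 (-1.49 ± 0.09). Tbr1 was higher in BP, at 400 ± 184 TPM (SD, n = 23) against 132 ± 71.4 (n = 27), as was Neurod1, at 197 against 81.0 TPM. Over all libraries the postmitotic neuron list summed to 7614 ± 1202 TPM in BP, 10560 ± 1338 in NBN and 3844 ± 2185 in NSC. Whether the BP fraction held neurons was not tested. The differences, Tbr1 and cell cycle genes included, are therefore between sorted fractions and not shown for dividing progenitors.

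Of the genes chosen by size of difference, those higher in BP were Calb2 (2.07 ± 0.09), a calcium binding protein, Tbr1 (1.85 ± 0.07), Prdm8 (1.85 ± 0.07), Dusp4 (1.84 ± 0.08), Reln (1.79 ± 0.10), the secreted protein of Cajal-Retzius neurons, Nhlh1 (1.77 ± 0.06), Sema3c (1.70 ± 0.10) and Cntn2 (1.70 ± 0.11). Tbr1 lies on chromosome 2 at 61802930 to 61814114 (GRCm38, protein coding). Those lower in BP were Dlx2 (-5.18 ± 0.16), Dlx1 (-5.16 ± 0.18), Hes5, Ednrb (-4.47 ± 0.08), Aldoc (-4.46 ± 0.10), Dlx5 (-4.28 ± 0.15), Mlc1 (-4.23 ± 0.08) and Cyr61 (-4.16 ± 0.11). Dlx genes, which specify ventral forebrain neurons, were part of a list of 13 interneuron and ventral forebrain genes, all 13 lower in BP (adjusted p = 0.13). That list summed to 585 ± 338 TPM in NSC libraries and 35.1 ± 18.8 in BP. Oligodendrocyte precursor genes were lower in 11 of 11 cases, such as Olig2 (-3.71 ± 0.11), astroglia genes in 13 of 20, Wnt pathway genes in 9 of 18 and BMP pathway and Id genes in 5 of 11 (adjusted p = 0.0825 each). Notch pathway genes were lower in 9 of 16 cases (adjusted p = 0.0878). Cajal-Retzius genes were higher in 7 of 9 cases (adjusted p = 0.0825), postmitotic neuron genes in 8 of 18 (adjusted p = 0.13), and axon growth and guidance genes in 10 of 18 (adjusted p = 0.171). In the basal progenitor list 1 of 14 genes, Neurod1, was higher (adjusted p = 0.877), and Eomes itself differed by 0.40 ± 0.09, under the minimum of 1. The direction for Eomes differed by stage. At E14.5 it ran from 300.9 to 498.2 TPM in NSC libraries and from 248.5 to 299.5 in BP. At E17.5 it ran from 532.4 to 737.2 in NSC and from 406.6 to 431.8 in BP. At E12.5, E15.5, E18.5 and PN every BP library was above every NSC library, and at E13.5 and E16.5 they overlapped. Whether the NSC fraction held BP was not tested. Dissociation stress genes were lower in 4 of 12 cases (adjusted p = 0.415), with sums of 446 ± 274 TPM in NSC and 206 ± 50.5 in BP libraries.

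In total 1255 of 15508 genes differed between BP and NSC by limma, 290 higher in BP and 965 lower (23.1% higher, or 33.3% after quantile normalization). No list passed 0.05 in the main setting. Without the filter on low values several did, such as the oligodendrocyte precursor and Wnt lists (adjusted p = 0.0246 each). With quantile normalization both of these also passed, as did the astroglia list (adjusted p = 0.0451 each). The count was 592 genes over stages up to E16.5 and 2865 from E17.5. Up to E16.5, Sema3c (0.62), Cntn2 (0.75), Neurod1 (0.78) and Top2a (-0.92) stayed under the minimum of 1.

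NBN libraries were compared with BP libraries over 5 shared stages, within the same reporter line. They were fitted as unpaired groups, though whether BP and NBN libraries share animals is not known. Postmitotic neuron genes were higher in NBN in 6 of 18 cases and lower in 1 (adjusted p = 0.811). Mapt, a microtubule protein, was at 1156 against 312 TPM, and the neurofilament gene Nefl differed by 3.07 on the log2 scale. Progenitor genes were lower, with 12 of 14 basal progenitor genes below the BP level (adjusted p = 0.2). Eomes, the gene of the reporter, fell from 438 ± 100 TPM in BP (SD, n = 14) to 25.1 ± 16.2 in NBN (n = 14). Cell cycle genes were lower in 20 of 28 cases (adjusted p = 0.209), with Mki67 at 3.86 against 27.5 TPM.

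The 8 genes with the largest higher values were Sla (4.36 ± 0.18), Ndrg1 (4.22 ± 0.14), Ntsr1 (4.15 ± 0.11), Mef2c (3.98 ± 0.14), a transcription factor of maturing neurons, Dync1i1 (3.87 ± 0.14), Gucy1a3 (3.74 ± 0.17), Ccbe1 (3.54 ± 0.12) and Lrfn5 (3.49 ± 0.12). Those with the largest lower values were Eomes (-4.56 ± 0.12, chromosome 9 at 118478212 to 118486132), Mfap4 (-4.40 ± 0.10), Tac2 (-4.35 ± 0.16), Nhlh1 (-4.07 ± 0.08), Neurod4 (-3.78 ± 0.11), Mfng (-3.24 ± 0.07), Loxl1 (-3.15 ± 0.11) and Btbd17 (-3.07 ± 0.09). Stem cell genes were lower in 9 of 20 cases (adjusted p = 0.811). Synapse and excitability genes were higher in 6 of 20 and lower in 2, the lower ones being Syn2 (-1.42 ± 0.09) and Slc17a6 (-1.99 ± 0.10), a vesicular glutamate transporter (adjusted p = 0.811). Cholesterol synthesis genes had a median of 0.62 with 1 of 16 higher (adjusted p = 0.2). Microglia genes were higher in 6 of 11 cases, at low levels, such as C1qa at 6.27 against 0.734 TPM (adjusted p = 0.3), which missed the minimum with a pseudocount of 5 (0.90). Whether microglia or their RNA were in the NBN libraries was not tested, here or against NSC.

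Between NBN and BP 1461 genes differed by limma, 676 higher and 785 lower (46.3% higher, or 54.4% with median ratio scaling and 54.3% with quantile normalization). No list passed 0.05.

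NBN were also compared with NSC over the same 5 stages. Cell cycle genes were lower in neurons in 26 of 28 cases, stem cell genes in 18 of 20 and Notch pathway genes in 14 of 16 (adjusted p = 0.107 each). Synapse genes were higher in 14 of 20 cases (adjusted p = 0.168) and postmitotic neuron genes in 14 of 18 (adjusted p = 0.159), such as Syt1 (2.65 on the log2 scale), a vesicle calcium sensor, and Stmn2 at 1303 against 310 TPM.

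Among the largest higher values were those of Sla (4.00 ± 0.17), Cck (3.52 ± 0.18), Dync1i1 (3.50 ± 0.13), Mef2c (3.24 ± 0.14), Ntsr1 (3.20 ± 0.11), Lrfn5 (3.16 ± 0.11) and Camk2b (3.13 ± 0.12). Lower were Hes5 (-5.28 ± 0.10), Fabp7 (-4.92 ± 0.12), Dlx1 (-4.83 ± 0.23), Dlx2 (-4.69 ± 0.20), Ednrb (-4.63 ± 0.10), Aldh1l1 (-4.58 ± 0.11), a folate enzyme of astrocytes, Tnc (-4.56 ± 0.13) and Aldoc (-4.47 ± 0.13). Interneuron and ventral genes were lower in 12 of 13 cases (adjusted p = 0.265) and ependymal genes in 5 of 7 (adjusted p = 0.251). Oligodendrocyte precursor genes were lower in 11 of 11 cases, astroglia genes in 16 of 20 and Wnt genes in 14 of 18 (adjusted p = 0.107 each). Microglia genes were higher in 6 of 11 cases (adjusted p = 0.168). Of 9 erythroid genes 4 were higher (adjusted p = 0.628), all adult globin genes with near-identical copies, whose values are uncertain. Upper layer genes were higher in 5 of 12 cases (adjusted p = 0.205), and deep layer genes in 3 of 12 with 2 lower (adjusted p = 0.384). Dissociation stress genes were lower in 5 of 12 cases (adjusted p = 0.609), with a sum of 191 ± 35.0 TPM in NBN libraries.

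Between NBN and NSC 2961 genes differed by limma, 1009 higher and 1952 lower (34.1% higher, or 49.4% after quantile normalization). The median of all genes was -0.125, and 0.04 after quantile normalization. No list passed 0.05 in the main setting. Without the filter on low values several did, such as the cell cycle and Notch lists (adjusted p = 0.0258 each). Up to E16.5 the count was 1567, and Cck did not pass there (0.51, adjusted p = 0.0796).

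Within NSC, the mid window (E13.5 to E15.5) was compared with the early window (E10.5 and E11.5). Neuronal genes rose in NSC libraries: 17 of 18 postmitotic neuron genes (adjusted p = 0.235), 17 of 18 axon genes and 19 of 20 synapse genes (adjusted p = 0.254 each). The postmitotic neuron list summed to 523 ± 74.8 TPM at E10.5 (n = 3) and 7317 ± 725 at E15.5 (n = 4). The transcription factor Neurod6 rose from 5.42 ± 6.92 TPM (SD, n = 6) to 692 ± 238 (n = 11). Hmga2, a chromatin protein, fell from 392 to 19.4 TPM, and Lin28a, which blocks let-7 maturation, from 34.1 to 0.09 TPM. Cell cycle genes fell in 17 of 28 cases (adjusted p = 0.254) and glycolysis genes in 11 of 14 (adjusted p = 0.102), with Ldha at 560 against 2063 TPM. A larger share of neuronal RNA in mid NSC libraries could contribute to the rises and in part to the falls. It was not separated from changes within the stem cells.

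Among genes chosen by size, Neurod6 (7.63 ± 0.14), Neurod2 (6.81 ± 0.13), Nfix (6.43 ± 0.18), Scand1 (5.93 ± 0.09), Aldoc (5.30 ± 0.18), Nfib (5.03 ± 0.14), Foxo6 (4.98 ± 0.12) and Rlbp1 (4.85 ± 0.10) rose. Nfix and Nfib are nuclear factor genes that act in gliogenesis. All of these risers but Aldoc were also high in NBN at E15.5. Their NSC to NBN ratios at that stage ran from 0.628 (Neurod2) to 1.797 (Rlbp1), with Nfix at 0.888 and Nfib at 0.835. The genes that fell furthest were the embryonic globin genes Hbb-bh1 (-9.32 ± 0.26), Hba-x (-9.00 ± 0.39) and Hbb-y (-8.12 ± 0.51), then Dlk1 (-5.42 ± 0.26), Crabp2 (-5.14 ± 0.16), Fezf1 (-4.80 ± 0.20), Hmga2 (-4.77 ± 0.17) and Lin28a (-4.32 ± 0.10). Erythroid genes fell in 8 of 9 cases (adjusted p = 0.235). Their sum was 6473 ± 2932 TPM at E10.5 and 92.3 ± 101 at E13.5. Single libraries ran from 3733 to 9566 TPM at E10.5 and from 1681 to 8836 at E11.5. Whether erythroid cells or their RNA entered the early libraries was not tested. The globin falls are therefore not shown to be changes within NSC. Meninges and choroid plexus genes fell in 7 of 9 cases and rose in 1 (adjusted p = 0.306), and 8 of 11 early heterochronic genes fell (adjusted p = 0.102). Basal progenitor genes rose in 7 of 14 cases (adjusted p = 0.306), deep layer genes in 8 of 12 (adjusted p = 0.306), upper layer genes in 8 of 12 (adjusted p = 0.235), astroglia genes in 7 of 20 with 2 lower (adjusted p = 0.571), and mitochondrial encoded genes in 5 of 13 (adjusted p = 0.549).

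From early to mid 2944 genes changed in NSC by limma, 2128 higher and 816 lower (72.3% higher, or 52.7% with median ratio scaling and 52.1% with quantile normalization). The median of all genes was 0.144, and -0.045 with median ratio scaling. No list passed 0.05 in the main setting, though the early heterochronic list did with array weights (adjusted p = 0.0405).

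From the mid to the late window (E17.5 to PN), glial genes rose in NSC. Olig1, a transcription factor of the oligodendrocyte lineage, rose from 5.02 ± 4.12 TPM (SD, n = 11) to 431 ± 248 (n = 9), and Apoe, an astrocyte lipoprotein, from 25.2 ± 9.96 to 1196 ± 807. All 11 oligodendrocyte precursor genes and 16 of 20 astroglia genes rose (adjusted p = 0.0351 each), among them Sox10 (4.84 on the log2 scale), Gfap (5.23), the astrocyte filament protein, and Aqp4 (4.23). Neuronal genes fell, in 12 of 18 postmitotic neuron cases with 1 higher (adjusted p = 0.157), with Tbr1 at 45.1 against 192 TPM. Hes5 rose from 108 to 328 TPM. A smaller share of neuronal RNA in late NSC libraries could contribute to these falls and rises, and was not separated from changes within the stem cells. At E15.5 genes high in NBN stood in NSC libraries at a median of 0.528 of their NBN level. Losing such a share could not alone give the median log2 rises of 4.29 (oligodendrocyte precursor list) and 3.04 (astroglia list). These values argue against it as the only source of the glial rises. Whether glial cells entered the late NSC fraction was not tested.

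**Figure D2:**
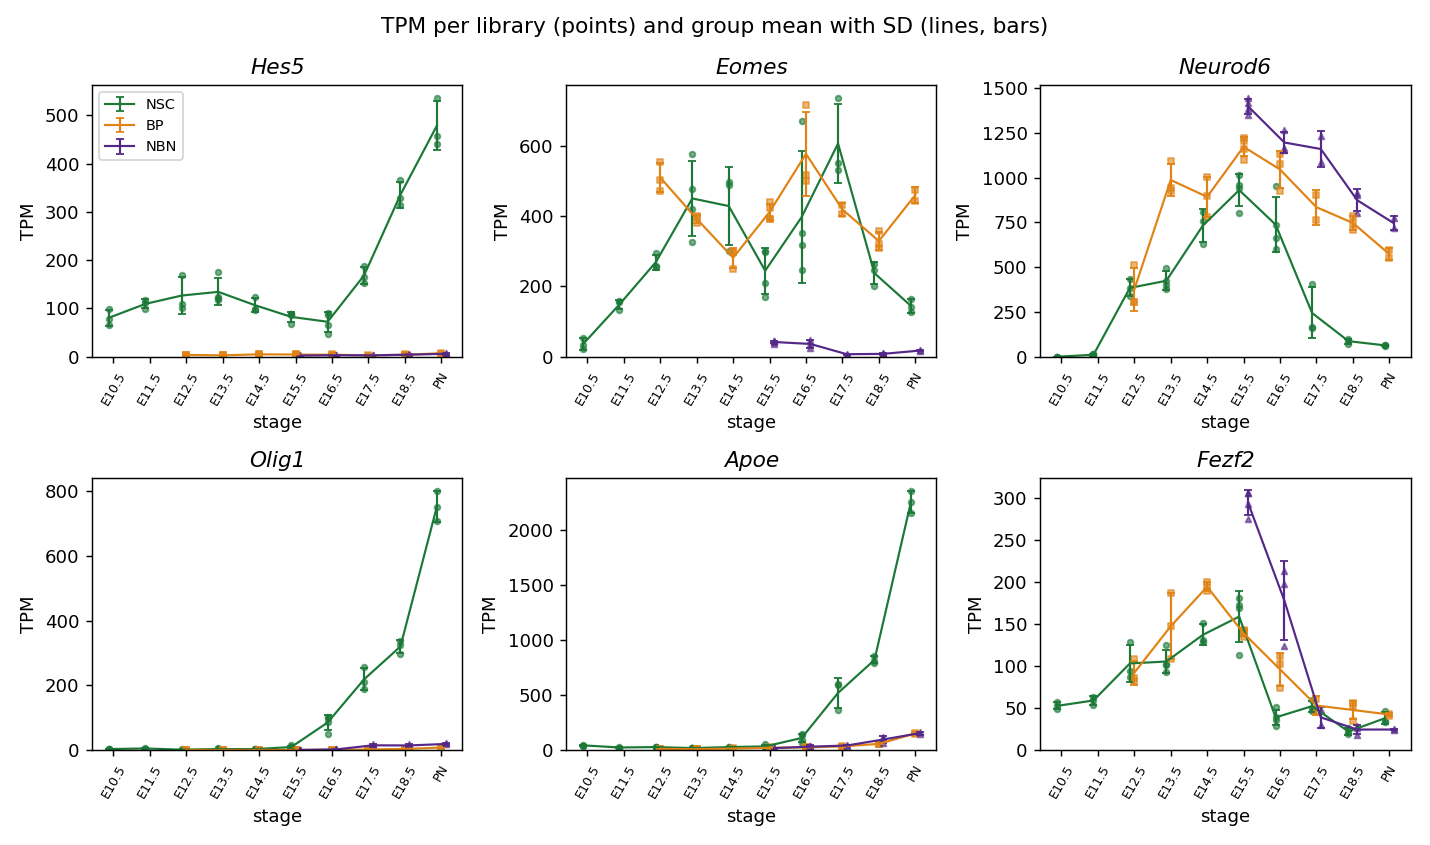
TPM (linear axes from 0) against stage for 6 genes, with points for libraries and lines for group means with SD. Olig1 and Apoe climb in late NSC, where their window means are 431 and 1196 TPM, Neurod6 is highest in NSC at E15.5, and Fezf2 falls in NBN.

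Risers chosen by size were Olig1 (6.25 ± 0.15, chromosome 16 at 91269772 to 91271933), Pdgfra (5.71 ± 0.13), the growth factor receptor of oligodendrocyte precursors, Hepacam (5.58 ± 0.09), Slco1c1 (5.54 ± 0.16), Tnc (5.49 ± 0.16), Sparcl1 (5.37 ± 0.13), Apoe (5.29 ± 0.14) and Gpr17 (5.23 ± 0.11). Fallers were Slc17a7 (-3.74 ± 0.12), a vesicular glutamate transporter, Ppp1r14a (-3.26 ± 0.17), Cabp1 (-3.12 ± 0.13), Reln (-3.08 ± 0.16), Sst (-3.04 ± 0.28), Neurog1 (-3.04 ± 0.14), Trp73 (-2.93 ± 0.13) and Cntn2 (-2.87 ± 0.17). Cajal-Retzius genes fell in 7 of 9 cases (adjusted p = 0.0927). Stem cell genes rose in 10 of 20 cases, Notch genes in 7 of 16 and Wnt genes in 8 of 18 with 1 lower (adjusted p = 0.447 each), BMP and Id genes in 5 of 11 (adjusted p = 0.386) and ependymal genes in 5 of 7 (adjusted p = 0.149). Dissociation stress genes rose in 6 of 12 cases (adjusted p = 0.447), and their sum went from 264 ± 44.0 TPM at E15.5 to 1136 ± 254 at PN. Endothelial and pericyte genes rose in 5 of 12 cases (adjusted p = 0.604), interneuron and ventral genes in 5 of 13 with 2 lower and meninges and choroid plexus genes in 3 of 9 (adjusted p = 0.832 each).

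From mid to late 1824 genes changed in NSC by limma, 1444 higher and 380 lower (79.2% higher, or 57.8% after quantile normalization). The median of all genes was 0.116, and -0.067 after quantile normalization. The astroglia and oligodendrocyte precursor lists did not pass with only the libraries compared (adjusted p = 0.17 and 0.26), with array weights (adjusted p = 0.0963 each) or with replicate number as a block (adjusted p = 0.0596 each), nor the precursor list with a mid window of E12.5 to E16.5 (adjusted p = 0.0539). The array weights were uneven, with 62.321 for NSC E17.5 replicate 3, so the E17.5 mean in that fit rested on that library.

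In BP, the same windows were compared. Late BP held more Zbtb20 and Prox1, transcription factors of the hippocampus and dentate gyrus, at 130 ± 91.2 against 18.1 ± 14.2 TPM and 56.9 ± 14.2 against 6.45 ± 2.73 (SD, n = 7 and 10). Upper layer genes Unc5d and Pou3f2 rose, by 2.48 and 2.18 on the log2 scale, while 4 of 12 deep layer genes fell (adjusted p = 0.131). Bcl11b fell by 2.23 and Fezf2 fell by 1.72 on the log2 scale. Upper layer genes rose in 3 of 12 cases and fell in 1 (adjusted p = 0.684), and early heterochronic genes fell in 5 of 11 (adjusted p = 0.0887).

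Tac2 (4.15 ± 0.20), Slco1c1 (3.65 ± 0.17), Dhrs3 (3.46 ± 0.18), Egr1 (3.38 ± 0.28), an immediate early gene, Stac2 (3.20 ± 0.20), Zbtb20 (3.13 ± 0.22), Prox1 (3.10 ± 0.17) and Grp (3.07 ± 0.21) rose most by the naming rule. Igf2bp2 (-2.92 ± 0.11), Cdh13 (-2.86 ± 0.18), Crabp2 (-2.84 ± 0.15), Lrfn5 (-2.75 ± 0.15), Kif26a (-2.60 ± 0.14), Slc17a7 (-2.54 ± 0.13), Ndrg1 (-2.52 ± 0.18) and Plxnd1 (-2.37 ± 0.17) fell most. Astroglia genes rose in 8 of 20 cases (adjusted p = 0.295), such as Aldh1l1 at 2.78 against 0.379 TPM, which missed the minimum with a pseudocount of 5 (0.53), oligodendrocyte precursor genes in 4 of 11 (adjusted p = 0.684), interneuron genes in 4 of 13 (adjusted p = 0.871) and stress genes in 3 of 12 (adjusted p = 0.807). Endothelial and pericyte genes rose in 3 of 12 cases (adjusted p = 0.767) and meninges and choroid plexus genes in 1 of 9 (adjusted p = 0.996). The sum of the latter list in BP libraries ran from 38.08 to 103.2 TPM at E15.5, 3.712 to 6.745 at E17.5, 34.51 to 404.4 at E18.5 and 435.6 to 817.8 at PN. No list passed 0.05 in the main setting. Without the filter on low values the early heterochronic and cholesterol synthesis lists did (adjusted p = 0.0346 each). By limma 730 genes changed, 510 higher and 220 lower (69.9% higher, or 56.4% with median ratio scaling and 49.9% with quantile normalization). The median of all genes was 0.122, 0.015 with median ratio scaling and -0.006 with quantile normalization.

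In NBN, E18.5 and PN were compared with E15.5 and E16.5. Deep layer genes fell in 8 of 12 cases (adjusted p = 0.00516). Fezf2, which specifies subcerebral projection neurons, fell from 245 ± 69.0 TPM (SD, n = 7) to 24.3 ± 3.82 (n = 5), and Bcl11b fell by 2.19 on the log2 scale. NBN of the later stages held more Cck, a neuropeptide, at 210 ± 26.9 against 30.1 ± 7.52 TPM. Upper layer genes were higher in 1 of 12 cases and lower in 3 (adjusted p = 0.735).

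Higher by the naming rule were Ptgds (3.48 ± 0.33), Grp (3.44 ± 0.25), Sema3c (2.84 ± 0.20), Cck (2.80 ± 0.29), Calb2 (2.60 ± 0.19), Nbl1 (2.54 ± 0.20), Zfp385b (2.51 ± 0.18) and Ttr (2.49 ± 0.76), a choroid plexus transcript whose libraries overlapped. Lower were Mc4r (-3.65 ± 0.24), Grik3 (-3.63 ± 0.34), Sox5 (-3.63 ± 0.18), Lrrtm3 (-3.33 ± 0.20), Hs3st4 (-3.31 ± 0.19), Kif26a (-3.20 ± 0.17), Fezf2 (-3.17 ± 0.15) and Prickle1 (-3.14 ± 0.17). Microglia genes rose in 7 of 11 cases (adjusted p = 0.0469), and their sum went from 6.53 ± 0.80 TPM at E15.5 to 83.4 ± 3.17 at PN. Whether microglia or their RNA entered the later NBN libraries was not tested. The microglia rise is therefore not shown to be a change within neurons. Interneuron genes rose in 6 of 13 cases (adjusted p = 0.574), oligodendrocyte precursor genes in 5 of 11 (adjusted p = 0.189), astroglia genes in 7 of 20 (adjusted p = 0.256), endothelial genes in 3 of 12 and stress genes in 2 of 12 (adjusted p = 0.574 each), and meninges and choroid plexus genes in 2 of 9 (adjusted p = 0.735).

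By limma 529 genes changed in NBN, 291 higher and 238 lower (55% higher, or 50.1% with quantile normalization). With a pseudocount of 5 the count was 199 (37.2% higher), with 0.1 it was 1238 (70.9% higher), and without PN 372 (43.8% higher). Between E15.5 and PN alone 1094 genes changed, and Ttr did not pass (adjusted p = 0.306). With only the libraries compared neither the deep layer nor the microglia list passed (adjusted p = 0.244 and 0.524). The microglia list also lost its call with a pseudocount of 0.1 (adjusted p = 0.0632), a filter of 5 TPM (adjusted p = 0.0745), array weights (adjusted p = 0.109), the replicate block (adjusted p = 0.0785), PN against E15.5 (adjusted p = 0.0646), a sex term (adjusted p = 0.0516), without the 4 libraries with most genes detected (adjusted p = 0.0629), without NBN E15.5 replicate 2 (adjusted p = 0.0513) and without NBN E18.5 replicate 2 (adjusted p = 0.0525).

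The change from mid to late was compared between BP and NSC as an interaction. Glial genes rose more in NSC. Pdgfra changed by 5.71 in NSC and 0.65 in BP, Sox10 by 4.84 and 0.32, and Olig1 by 6.25 and 2.01. Reln changed by -3.08 in NSC and -0.38 in BP, and Sema3c by 0.31 in NSC and 2.89 in BP. The NSC changes carry the limits given above, a possible change in the share of neuronal RNA and possible glial cells in the late fraction. For the glial lists the former alone was too small.

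Differences of change, BP minus NSC, were largest for Sst (3.01 ± 0.42), Nrp1 (2.87 ± 0.22), Cldn3 (2.86 ± 0.25), Nos1 (2.85 ± 0.25), Grp (2.72 ± 0.28), Reln (2.70 ± 0.24), Sema3c (2.58 ± 0.23) and Calb2 (2.49 ± 0.22). On the other side stood Pdgfra (-5.06 ± 0.19), Serpine2 (-5.02 ± 0.17), Gpr17 (-4.94 ± 0.17), Sox10 (-4.53 ± 0.15), Cntn1 (-4.51 ± 0.17), Olig1 (-4.25 ± 0.23), Gdf10 (-3.93 ± 0.20) and Hepacam (-3.90 ± 0.14). The astroglia list was lower in 17 of 20 cases and higher in 2, Nfix and Nfib, and the oligodendrocyte precursor list was lower in 10 of 11 (adjusted p = 0.0103 each). Cajal-Retzius genes were higher in 8 of 9 cases and cholesterol synthesis genes lower in 5 of 16 (adjusted p = 0.0583 each), and cell cycle genes were lower in 14 of 28 (adjusted p = 0.294). The interaction passed for 1505 genes by limma, 443 higher and 1062 lower (29.4% higher, or 38.8% with quantile normalization).

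Between consecutive stages the NSC libraries changed most from E16.5 to E17.5, with 1913 genes by limma, 974 higher and 939 lower. In single NSC libraries the postmitotic neuron sum ran from 4652 to 7251 TPM at E16.5 and from 2318 to 3652 at E17.5. A change in the share of neuronal RNA was not separated from a change within the stem cells. The steps from E10.5 to E11.5 and from E11.5 to E12.5 gave 1384 and 1355 genes. The step from E12.5 to E13.5 gave 614, but 222 without E12.5 replicate 3 and 1061 without E12.5 replicate 2. The step from E13.5 to E14.5 gave 416 (637 without E14.5 replicate 1), and that from E14.5 to E15.5 gave 343 (199 without E14.5 replicate 1, 662 without replicate 3). In BP the steps gave 34 to 408 genes and in NBN 61 to 286. The BP step from E15.5 to E16.5 gave 34, but 3, 75 and 60 without E16.5 replicates 1, 2 and 3. That from E13.5 to E14.5 gave 301, but 457 and 532 without E13.5 replicates 2 and 3 and fewer, by over 1.5 times, without replicate 1. Without BP E17.5 replicate 1 the steps before and after E17.5 gave 96 and 18 in place of 193 and 76. The latter was 46 without BP E18.5 replicate 1 and 142 without replicate 3, and E18.5 to PN gave 146, or 97 without PN replicate 2. In NBN the step from E15.5 to E16.5 gave 61 (127 without E16.5 replicate 1) and the next 286, which dropped by over 1.5 times without E17.5 replicate 1.

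**Figure D3:**
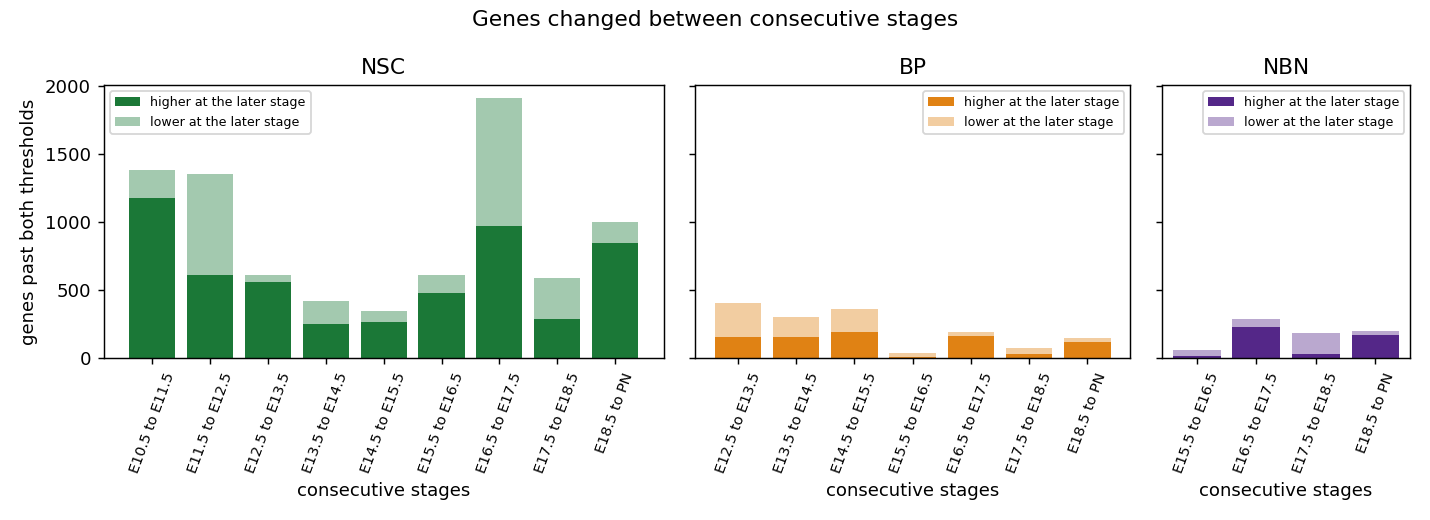
Bars (from 0) give the number of genes past both thresholds between consecutive stages in each kind of sorted cell, split by direction. The NSC step from E16.5 to E17.5 has 1913 genes, while no BP step exceeds 408.

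Over the 8 contrasts 6 of 200 list tests passed with an estimated correlation, against 110 with the preset one. Counts adjusted over the list alone equalled those over all genes tested in every list and contrast except 1, the meninges and choroid plexus list in BP, where 1 gene passed over all genes and 0 over the list. The 8 counts rest on the fold minimum: of 1260 genes past it between BP and NSC only 5 missed the adjusted p threshold, and of 541 in NBN only 12 did.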

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

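The tests on Y-linked transcripts and on the interneuron list were chosen only after the results were seen, while those on other splits of the samples were not. The tests on neuronal ratios and scaling address a pattern defined by E15.5 and E16.5, the stages of the neuronal peak in NSC libraries. They are therefore not taken as chosen before that peak was seen.

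The labels call every sample female, yet 43 of 70 libraries held at least 10 TPM of Y-linked transcripts. That value excludes material from females alone for those libraries, so the sex label may be wrong. In 20 libraries both Xist and the Y-linked sum reached 5 TPM, in line with pools of both sexes. The Y-linked list had 4 genes. A term for sex left the count between BP and NSC at 1285 genes.

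Neuronal transcripts in NSC libraries peaked at E15.5 and E16.5. Scaling did not account for the rise from the early to the mid window, since the median change of the postmitotic neuron list was 2.13 or more under the other scalings. E16.5 lies outside these windows, and the peak itself was not tested under another scaling. If neurons or their RNA were in the NSC libraries, genes high in NBN would share 1 ratio. At these stages 87% of such gene values lay within a factor of 2 of the stage median, which was 0.528 at E15.5 and 0.546 at E16.5. This is consistent with neurons, or with progeny that still carry GFP, in the sorted NSC fraction. The test does not separate these, and a change within the stem cells stays open and was not tested.

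Interneuron and ventral genes were higher in NSC than in BP libraries. If ventral cells or interneurons entered some NSC libraries, members would vary together between replicates. Their median pairwise correlation over 33 NSC libraries was 0.805, against at most 0.528 in 1000 random lists. A variable share of such cells would give this. The random lists were matched on level only, so genes regulated together within the stem cells would give it too. The test cannot separate these readings. Dlx1 and Dlx2 reached 170 and 147 TPM on average, and the dissection was of dorsal cortex. A sort on Hes5::GFP would remove postmitotic interneurons unless they still carry GFP, but not ventral stem cells that the dissection left in. Expression by dorsal stem cells and an effect of the reporter line stay open.

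The change from mid to late differed between BP and NSC for 1505 genes, by a test of the difference itself. Values for named genes were 3.01 for Sst, 2.87 for Nrp1, 2.86 for Cldn3, 2.85 for Nos1, 2.72 for Grp, 2.70 for Reln, 2.58 for Sema3c and 2.49 for Calb2. They were -5.06 for Pdgfra, -5.02 for Serpine2, -4.94 for Gpr17, -4.53 for Sox10, -4.51 for Cntn1, -4.25 for Olig1, -3.93 for Gdf10 and -3.90 for Hepacam.

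In groups of 4, 1 library lay far from the others in 8 of 150 tests, near the 1 in 20 that chance gives. NSC E13.5 replicate 1 stood apart in Hes5 (175.9 TPM), the erythroid sum (242.5 TPM) and the share of the 10 highest genes (8.165%). Others were NSC E15.5 replicate 4 in Hes5 (66.87 TPM), NSC E15.5 replicate 3 in the endothelial sum (29.66 TPM), NSC E16.5 replicate 4 in the basal progenitor sum (2614 TPM), BP E15.5 replicate 2 in the cell cycle sum (1130 TPM) and BP E15.5 replicate 1 in the Y-linked sum (0.214 TPM).

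Other splits of the samples were counted, 100 per contrast with the real one included. In each contrast 1 split, the real one, gave as many genes. With 100 splits this share cannot go below 1 in 100. The splits treat libraries as separate samples, which the labels do not state. They therefore do not exclude chance for any gene, nor effects of shared animals. Real and highest other counts were 1255 and 172 for BP and NSC, 1461 and 253 for NBN and BP, 2961 and 1903 for NBN and NSC, 2944 and 1377 for NSC early to mid, 1824 and 526 for NSC mid to late, 730 and 341 for BP, 529 and 321 for NBN, and 1505 and 577 for the interaction.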

How the results depend on the processing

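The alternatives without the 4 libraries with most genes detected, with a sex term, without E15.5 and E16.5 and without PN were chosen after seeing the data. The counts of genes rest on the fold minimum: of 1260 genes past it between BP and NSC 5 missed the adjusted p threshold, and of 541 in NBN 12 did. Settings that change only the variance could not move these counts, so that they agree says nothing about stability. No named gene that was called and no list that passed changed direction, but lists that did not pass did. The larger side turned for NBN and BP (46.3% higher, 54.4% with median ratio scaling), BP mid to late (69.9%, 49.9% with quantile normalization) and NBN (55%, 37.2% with a pseudocount of 5, 43.8% without PN). The median of all genes changed sign in all 8 contrasts under some setting, as from 0.122 to -0.006 in BP with quantile normalization. With a pseudocount of 0.1 the counts rose to 2031 for BP and NSC, 2256 for NBN and BP, 2788 for NSC mid to late, 1534 for BP and 1238 for NBN. With a pseudocount of 5, which shrinks low genes, they were 634 for BP and NSC, 729 for NBN and BP, 1791 for NBN and NSC, 1625 for NSC early to mid, 918 for NSC mid to late, 285 for BP, 199 for NBN and 780 for the interaction. Array weights were uneven, with 62.321 for NSC E17.5 replicate 3, 17.944 for NSC E12.5 replicate 1 and 0 for NSC E10.5 replicate 2. Without a fold minimum the counts were, in the same order, 11818, 10821, 12551, 11958, 10873, 9311, 6638 and 8088. Up to E16.5 BP and NSC gave 592 and NBN and NSC 1567, and from E17.5 BP and NSC gave 2865. PN against E15.5 gave 1094 in NBN. The cause of the differences between stages was not tested. The other planned and added settings kept all 8 counts within 1.5 times, among them 1845 for BP and NSC and 2501 for NSC early to mid without E15.5 and E16.5.

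Leaving out 1 library at a time gave 1229 to 1302 genes for BP and NSC, 1412 to 1491 for NBN and BP, 2914 to 3015 for NBN and NSC, 2840 to 3107 for NSC early to mid, 1770 to 1895 for NSC mid to late, 700 to 778 for BP, 519 to 551 for NBN and 1443 to 1610 for the interaction. Libraries of BP and NBN with the same replicate number had a median correlation of 0.124 over 14 pairs, 8 of them above 0.1 and the lowest -0.234, against -0.032 over 28 pairs with different numbers, the highest 0.402. The correlations are of deviations from group means. In groups of 2 these mirror each other, so E17.5 and PN each gave 1 value, 0.124 and 0.363, repeated with either sign. The pairs are therefore not independent. Each E15.5 BP library correlated best with its own number, as not all did at E16.5 and E18.5. Xist and Y-linked levels went with the number at E15.5, E17.5 and PN but not at E18.5, which speaks against the number there and not against shared animals. At E18.5 BP replicates 1, 2 and 3 correlated best with NBN replicates 2, 3 and 1 (0.118, 0.215 and 0.402), whose Xist levels held the same rank. At E16.5 all BP and NBN libraries held Xist (120.9 to 351.1 TPM) and at most 0.4262 TPM of Y-linked transcripts, which cannot tell numbers apart. BP and NBN thus held alike mixes of sex transcripts at each shared stage, as shared animals would give, but no label states sharing. The numbers were not taken as pairs, and whether these libraries share animals stays open. The replicate block below goes by number, so these E18.5 matches were not fitted as pairs. With the replicate block (stage and number between cell types, number within cell type over time, number for the interaction) the counts were 1207, 1461, 2894, 2989, 1867, 731, 520 and 1512, in the order above. BP and NBN had the same replicate numbers at each shared stage, so the block left their estimated differences unchanged. Since that count rests on the fold minimum, 1461 could hardly move and says nothing about pairing. Among the list tests 16 calls were lost and 40 gained under settings other than leaving out a library, and 2 were lost and 12 gained when 1 was left out. Sequencing depth is unknown, so its limits on low genes could not be assessed.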

Other observations

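Prox1 and Zbtb20 were noticed in late BP first, and the test below was chosen after that but before its own values were seen. A candidate explanation for their rise is a larger share of hippocampal or dentate cells in late BP libraries. A list of other hippocampal genes, written down before the test, did not decide it, since limma's camera, with 1 list tested, gave an adjusted p = 0.606. The median change of the list was -0.04, and members went both ways, from Fzd9 (-0.81) and Lef1 (-0.75) to Emx2 (0.67) and Man1a (1.01). The bound set before the test, a median of 0 or less, would have counted this median against the explanation. That bound was wrong because a median this close to 0, over members spread so widely, excludes nothing, and the reading was changed after the value was seen. The explanation stays open.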
